A study of Mus musculus with 9 samples.

How the data were processed

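Polyadenylated RNA from whole mouse retina was sequenced in 9 libraries, 3 from wild type mice, 3 from rd10 mice and 3 from mice labelled as expressing green fluorescent protein (GFP). Each library held 2 retinae. Per the labels, the messenger RNA was fragmented and reverse transcribed from random hexamers. The wild type mice were taken at postnatal day 48 and the rd10 mice at day 61. A line written as Gg13 was taken at day 42. It was read here as the GFP group, the only group left without an age. Age therefore coincided fully with genotype and could not be a term of the model. The label of genetic background also differed between the GFP and wild type groups. Per the labels, the replicates were biological.

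The deposited files held 1 count per gene and library, and the authors' values were read as raw counts, since all of them were whole numbers and their totals differed between libraries. Reads had been counted by the authors on the mouse build mm9. The aligner, the counting program, the annotation, the strand setting and the treatment of reads with several matches were not given in the sources used here. Each file listed the same 21769 genes, all with a gene name, and 4230 of them had a count of 0 in all 9 libraries. Totals per library ran from 9597635 to 12149448 counts, so that 1 CPM, a count scaled to a library total of 1000000, stood for 9.60 to 12.2 counts. Chi-square per degree of freedom between replicate libraries of a group lay between 13.6 and 80.1, so the replicates differed by more than repeated sequencing of one library would give. Intervals and floors given with single values cover counting error only.

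Genes were kept by filterByExpr of edgeR 4.0.16 in R 4.3.3 with a minimum count of 10 and a minimum total of 15, which left 14300 genes. Library sizes were scaled by the trimmed mean of M values (TMM). A single edgeR model with 1 mean per group was fitted to the 9 libraries, and each pair of groups was compared by edgeR's quasi-likelihood F-test. P values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were counted as higher or lower, also with a change of at least 2-fold. Adjusted p values in the text come from this test unless another is named. CPM values were TMM-scaled. Genomic positions are those of the deposited files on mm9, with 1 added to each start. Where a group had no count of a gene, the fold was bounded by a floor of 3 counts per library. Where a group had 1 to 3 counts in all, the ratio of counts per total was given with its exact 95% interval.

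The choices above, 28 gene lists, the genes to be named and the first alternatives were fixed before the data were examined. The lists took textbook markers of retinal cell types and of other tissues near the retina, and genes of a few pathways. Of 436 entries, 434 were matched to a gene in the files, 3 of them through an older symbol. Lists with at least 3 tested genes were compared with all other genes by camera (limma 3.58.1, on log2 CPM with a prior count of 2) with a preset correlation between genes of 0.01, and again with an estimated correlation. The rotation test fry, which asks whether the genes of a list move on balance one way, was run beside them. Unlike camera, fry does not compare a list with other genes. List p values were adjusted over the lists of a comparison. The sex-linked list was read as values and not tested. In rd10 against wild type, the genes to be named were 10 fixed genes, the 6 highest and 6 lowest log2 fold changes among genes past the threshold with a mean of at least 5 CPM and no overlap between the groups' libraries, and up to 4 genes per list with the smallest adjusted p. Where no gene of a list passed, the one with the highest mean CPM was named. The fixed and extreme genes were also named in rd10 against GFP. In GFP against wild type, Gng13, up to 8 extreme genes in each direction and genes of lists past the list test were to be named. Some genes chosen by these rules are not reported here. No predicted locus had to be skipped (count 0).

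The procedure was first tested on simulated data with the group sizes and depths of these libraries. For rd10 against wild type it recovered 0% of genes changed 1.5-fold, 26.9% of genes changed 2-fold and 86.2% of genes changed 4-fold, and it called 0.0437% of unchanged genes. For the other comparisons it recovered 33.3% and 34.3% of genes changed 2-fold. It called all 10 shifted lists in each comparison, and at most 1 of 10 unshifted lists. The simulated genes were drawn independently and their lists at random, while the estimated correlation was 0.535 in the rod list and 0.881 in the lens list. The simulation therefore does not show how often camera with its preset correlation calls unchanged lists of correlated genes. For rd10 against wild type, changes of 1.5-fold, 2-fold and 4-fold were set in only 66, 67 and 65 of 13915 genes. The adjustment is stricter there than where many genes change, so these shares need not hold for the rd10 comparisons.

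The alternatives fixed in advance were 4 other scalings, DESeq2 1.42.0, limma-voom, 2 other filters on low counts, a fit of the compared groups alone, the replicate number as a block, other list tests, and leaving out each library in turn. After the data were seen, 5 alternatives were added: leaving out the 4 libraries with lens transcripts, the lens transcript level as a covariate, leaving out wild type 3 and GFP 2, removal of each library's trend with transcript length, and a covariate for the 2 libraries with Xist. Transcript lengths came from a reference annotation and were found for 99.0% of the tested genes.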

Results

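Gene expression was measured in whole retina of 3 groups of mice, with 3 libraries in each. The rd10 strain carries a mutation of Pde6b, which encodes a subunit of the phosphodiesterase of rod photoreceptors, and its rods degenerate after birth. The labels call the retinae of the wild type and GFP groups normal. Library totals were 10455199, 11629409 and 10037144 counts in wild type, 10861517, 10571532 and 12149448 in rd10, and 11856196, 9597635 and 11454731 in GFP. Glul, the glutamine synthetase of Müller glia, had the highest count in each rd10 library, with 0.556% to 0.590% of counts. The genes of the rod, cone and shared photoreceptor lists held 11.9% to 14.4% of counts in the normal libraries and 0.683% to 0.833% in the rd10 libraries. The first principal component held 53.9% of the variance and separated rd10 from both normal groups, and the second held 17.3%, with wild type 3 at -28.6 and GFP 2 at -54.5, below the other normal libraries.

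The comparison of rd10 with wild type asked how the retinal transcriptome differed in the degenerating retina. Transcripts of rods were nearly lost in rd10, and genes shared by rods and cones were strongly reduced. Many transcripts of bipolar, amacrine and ganglion cells and of Müller glia were more abundant, by up to 2.64-fold among the genes named. These values are TMM-scaled shares of counts, not amounts per cell or per retina. A lower share of rod RNA may account for the higher inner retinal lists, as weighed under other observations. However, 6 of 13 ON bipolar, 4 of 9 OFF and other bipolar and 9 of 14 ganglion cell genes did not pass. None of the bipolar, amacrine, ganglion and Müller lists passed camera with an estimated correlation (adjusted p = 0.0607 to adjusted p = 0.103). Among genes of reactive glia, microglia and complement, 15 of 19, 13 of 20 and 10 of 15 rose, and 1 complement gene fell. The largest rise among the genes named from the gliosis, microglia and complement lists was 21.8-fold, for Serpina3n. These lists did not pass with an estimated correlation either (adjusted p = 0.0662, adjusted p = 0.0607 and adjusted p = 0.129). By fry, the bipolar, amacrine, ganglion, Müller, gliosis, microglia and complement lists all passed (adjusted p from 8.38e-05 to 6.03e-04). Fry does not compare a list with other genes, many of which also changed here. Most cone genes did not pass the test. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 2067 genes were higher and 1988 lower in rd10, of which 899 and 983 changed at least 2-fold. The libraries of the groups did not overlap for 50.5% of genes, where chance gives 10%.

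All 16 genes of the rod list fell in rd10, with a median log2 fold change of -6.18. Pde6b (chromosome 5, 108817392 to 108860761) fell from 3153 ± 506 CPM in wild type to 19.6 ± 12.3 CPM in rd10 (SD, n = 3 libraries each), with a log2 change of -7.33 (SE 0.54) and an adjusted p of 5.18e-06. Gnat1, the alpha subunit of rod transducin, fell from 23150 ± 5297 to 140 ± 92.9 CPM, and Nrl, the transcription factor that directs rod fate, was 180.7-fold lower. Cngb1, Guca1b, Reep6 and Sag had the smallest adjusted p of the list and were 21.1-fold, 118.8-fold, 44.0-fold and 28.0-fold lower. The 26 genes shared by rods and cones all fell too, with a median of -3.92. Prph2, which shapes the outer segment disc, was 37.6-fold lower, Pdc, the phosducin gene, 47.1-fold lower, and the fascin gene Fscn2 153.3-fold lower. Adjusted over the list alone, 16 and 26 genes of these lists were lower. By camera, the adjusted p was 9.71e-21 for the rod list and 3.35e-29 for the shared list, and for both the adjusted p = 0.0607 with an estimated correlation.

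Hdc, Nipal1, Sh2d1a and Slc17a3 were also among the 6 lowest changes and were close to absent in rd10. Hdc, which encodes histidine decarboxylase, had 3 counts over the 3 rd10 libraries, 2 of them in rd10 1, against 885 in wild type, a ratio of counts per total of 377 with an exact 95% interval from 128.4 to 1829. The ratio was 240 (95% interval 66.0 to 1989) for Nipal1 and 259.8 (71.5 to 2152) for Sh2d1a, each with 2 counts in rd10, both in rd10 2. Slc17a3 had 1 count in rd10, in rd10 3, and a ratio of 286 (50.8 to 11340).

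Of 13 cone genes, 1 rose, 2 fell and 10 did not pass the test, and the counts adjusted over the list alone were 1 and 2. Opn1sw, the short-wavelength cone opsin, fell from 488 ± 45.9 to 221 ± 8.52 CPM (SD, n = 3), with a log2 change of -1.15 and an adjusted p of 3.92e-04, and it overlaps Calu on the genome. Thrb, the thyroid hormone receptor of cones sensitive to medium wavelengths, was 2.05-fold lower, and Pde6c, the cone phosphodiesterase, was 1.89-fold higher. Opn1mw, the medium-wavelength opsin, had 181 ± 14.8 CPM in rd10 and 204 ± 48.03 CPM in wild type, a log2 difference of -0.18 with an adjusted p of 0.603. Arr3, cone arrestin, had a log2 difference of -0.21 with an adjusted p of 0.638. Scaled by library totals these differences were 0.11 and 0.06, and the median of the cone list turned from -0.13 to 0.15. The list did not pass camera (adjusted p = 0.913, and adjusted p = 0.955 with an estimated correlation).

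**Figure D1:**
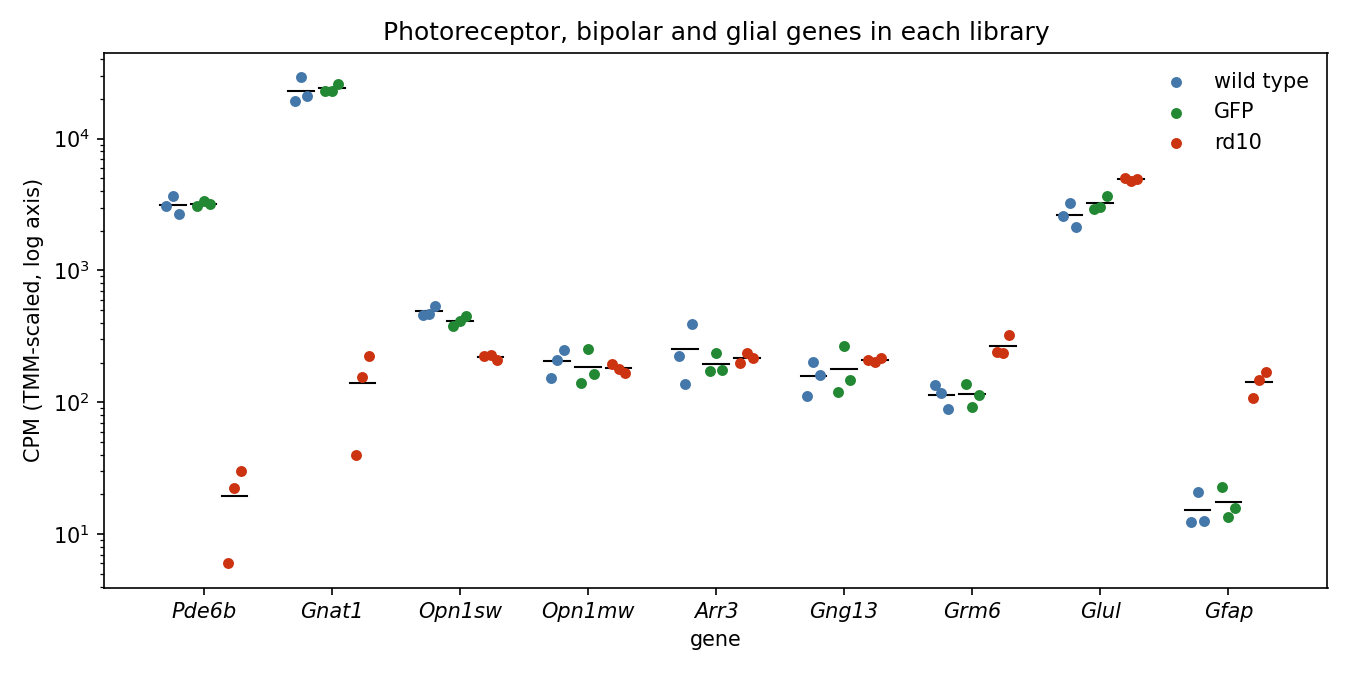
CPM (TMM-scaled, log axis) of 9 of the genes fixed in advance in each library, with 1 point per library, a bar at the mean of the 3 libraries of a group, and colours for wild type, GFP and rd10. Gnat1 lay near 23150 CPM in wild type and 140 CPM in rd10, and Gfap near 15.3 and 142 CPM.

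Some genes of the inner retinal neurons were higher in rd10 as scaled shares of counts, and others did not pass. Of 13 ON bipolar genes, 7 rose, none fell (0) and 6 did not pass, with 8 higher adjusted over the list alone. Grm6, the glutamate receptor of ON bipolar cells, rose from 114 ± 22.9 to 266 ± 49.4 CPM (SD, n = 3), a log2 change of 1.23 with an adjusted p of 0.00237. Isl1 rose 2.20-fold, Gpr179 2.12-fold and Cabp5 1.78-fold. Gng13, a G protein subunit of ON bipolar cells that overlaps Chtf18, had a log2 difference of 0.40 that did not pass (adjusted p = 0.323), but it passed once the trend with transcript length was removed (0.83, adjusted p = 0.00268, over a range of alternatives from 0.00268 to 0.590). Of 9 genes of OFF and other bipolar cells, 4 rose, 1 fell and 4 did not pass, with 7 higher and 1 lower adjusted over the list alone. Vsx1, Grik1 and Tacr3 rose 1.99-fold, 1.98-fold and 2.01-fold. The gene that fell was Otx2, a transcription factor of bipolar cells and photoreceptors named after its value was seen, with a log2 change of -0.65. Of 6 horizontal cell genes, Lhx1 and Onecut2 rose 2.37-fold and 2.36-fold, 4 did not pass, and 3 were higher adjusted over the list alone. Onecut2 lost its call with the length trend removed (adjusted p = 0.162, over a range of alternatives from 8.84e-05 to 0.194). The list test gave an adjusted p of 0.00111 for ON bipolar, 0.00507 for OFF and other bipolar and 0.0689 for horizontal cells. In that order camera gave adjusted p = 0.0607, adjusted p = 0.103 and adjusted p = 0.170 with an estimated correlation.

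Of 17 amacrine cell genes, 13 rose and 4 did not pass, also with 13 adjusted over the list alone. Slc5a7, the choline transporter of cholinergic cells, rose 2.09-fold, and Gad2 and Slc32a1, which serve GABA synthesis and vesicle loading, rose 1.66-fold and 1.64-fold. Of 14 ganglion cell genes, 5 rose and 9 did not pass, with 9 higher adjusted over the list alone. Rbpms rose 1.96-fold, Pou4f1 1.89-fold and Slc17a6, a vesicular glutamate transporter, 1.84-fold. Of 21 glutamate, GABA and glycine receptor genes of the inner retina, 16 rose and 5 did not pass, also with 16 adjusted over the list alone. Grm5, Grik2 and Gria1 rose 3.05-fold, 2.47-fold and 1.99-fold. Camera's adjusted p was 1.74e-05 for amacrine cells, 2.86e-04 for ganglion cells and 9.58e-08 for the receptors. With the lists in this order, camera gave adjusted p = 0.0607, adjusted p = 0.0662 and adjusted p = 0.0607 with an estimated correlation.

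Most Müller glia genes rose as scaled shares of counts. Of 15, 13 rose and 2 did not pass, with 14 higher adjusted over the list alone and a median log2 fold change of 1.04. Glul rose from 2655 ± 549.6 to 4927 ± 169 CPM (SD, n = 3), a log2 change of 0.89 (SE 0.18) with an adjusted p of 0.00549. Sox9, a transcription factor of these glia, rose 2.64-fold, the water channel gene Aqp4 2.46-fold, the glutamate transporter gene Slc1a3 2.08-fold and Dkk3 2.11-fold. Of 19 genes of reactive gliosis, 15 rose and 4 did not pass, with 18 higher adjusted over the list alone and a median of 1.92. Gfap, the intermediate filament of reactive glia, rose from 15.3 ± 4.82 to 142 ± 31.9 CPM (SD, n = 3), a log2 change of 3.21 (SE 0.29) with an adjusted p of 2.05e-05. Serpina3n, a protease inhibitor gene, rose 21.8-fold from 6.35 ± 2.13 to 139 ± 35.8 CPM. A2m rose 12.5-fold and the cytokine receptor gene Osmr 5.17-fold. Camera gave an adjusted p of 6.13e-07 for Müller glia and 3.75e-10 for gliosis. Camera then gave adjusted p = 0.0607 and adjusted p = 0.0662 with an estimated correlation.

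Most tested genes of microglia and of complement were higher. Of 20 microglia and macrophage genes, 13 rose and 7 did not pass, with 15 higher adjusted over the list alone. Itgam, Ctss, C1qc and Csf1r, the receptor of a growth factor of macrophages, rose 4.38-fold, 3.12-fold, 3.06-fold and 2.76-fold. Of 15 tested complement genes, 10 rose, 1 fell and 4 did not pass, with 12 higher and 1 lower adjusted over the list alone. C4b rose from 13.2 ± 4.96 to 253.9 ± 52.1 CPM (SD, n = 3), a log2 change of 4.26 with an adjusted p of 1.36e-05. C4a is a near-identical copy of it on the genome. Serping1, an inhibitor of the first complement component, rose 7.05-fold and C3 6.55-fold. The gene that fell was Cd59a, an inhibitor of complement named after its value was seen, with a log2 change of -0.67. C1qa, C1qb and C1qc stand in both lists. By camera, the adjusted p was 2.72e-07 for microglia and 8.45e-06 for complement. For these lists in turn it gave adjusted p = 0.0607 and adjusted p = 0.129 with an estimated correlation.

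Of 27 genes of the interferon response and antigen presentation, 13 rose, 1 fell and 13 did not pass, with the same counts of 13 and 1 adjusted over the list alone. H2-Eb1, of the class of molecules that present antigen to helper T cells, rose 13.7-fold, Cd74, the chaperone of this class, 6.11-fold and Gbp2 3.90-fold. The gene that fell was Irf7, a transcription factor of the interferon response named after its value was seen, with a log2 change of -1.48. Of 20 tested cell death genes, 5 rose and 15 did not pass, also with 5 adjusted over the list alone. Casp12 had no count in wild type and was at least 8.79-fold higher in rd10, against a floor of 3 counts per library. Casp1, with 2 counts in wild type, both in wild type 1, and 82 in rd10, had a ratio of 32.1 (95% interval 8.61 to 269.7). Tnfrsf1a, a receptor of tumour necrosis factor, rose 3.07-fold and Capn2 1.66-fold. The median of the list was 0.42, also with Casp12 at its bound. The list test gave an adjusted p of 4.5e-06 for the interferon list and 0.0153 for cell death. In the same order, camera gave adjusted p = 0.186 and adjusted p = 0.170 with an estimated correlation.

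Some genes of the metabolic and synaptic lists were lower. Of 22 genes of glycolysis and lactate transport, 10 fell, 2 rose and 10 did not pass, with 13 lower and 2 higher adjusted over the list alone. Hk2, a hexokinase, was 7.73-fold lower, Ldha 3.67-fold lower, and the lactate transporter genes Slc16a3 and Slc16a1 3.31-fold and 2.93-fold lower. The 2 genes that rose were Pfkm and Slc16a8, a lactate transporter of the pigment epithelium, named after their values were seen. Of 14 ribbon synapse genes, 10 fell and 4 did not pass, also with 10 adjusted over the list alone. Cabp4, a calcium-binding protein of photoreceptor terminals, was 20.9-fold lower, Cplx4 10.1-fold, Elfn1 4.55-fold and Stx3 3.02-fold. Of 22 respiratory chain genes, 6 fell and 16 did not pass, also with 6 adjusted over the list alone, Ndufa10 being 1.81-fold lower. Calls of other genes that fell were lost with library totals (adjusted p = 0.166 and adjusted p = 0.171) and without single libraries. Camera's adjusted p was 7.47e-04 for glycolysis, 1.11e-04 for ribbon synapse and 0.00116 for the respiratory chain. With the lists in this order, camera gave adjusted p = 0.364, adjusted p = 0.170 and adjusted p = 0.474 with an estimated correlation. The call of the respiratory chain list ended with fry (adjusted p = 0.0672), without the 4 libraries with lens transcripts (0.0951) and with the trend of transcript length removed (0.385), over a range of alternatives from 1.03e-04 to 0.474.

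Among the other lists, 2 of 18 antioxidant genes rose (Sod3 3.42-fold, Gpx3 3.81-fold), 1 fell (Gpx4) and 15 did not pass, with the same counts of 2 and 1 adjusted over the list alone. Gpx4 was 1.96-fold lower and lost its call without rd10 2 (adjusted p = 0.0516, over a range of alternatives from 7.08e-04 to 0.414). Of 15 clock genes, 4 rose, 2 fell and 9 did not pass, with 8 higher and 2 lower adjusted over the list alone. Hlf rose 2.18-fold and Arntl, the partner of Clock, was 2.17-fold lower. Of 12 immediate early genes, 1 rose (Egr1), 1 fell (Atf3) and 10 did not pass, with 1 and 1 adjusted over the list alone. Atf3 had a log2 change of -2.45, and of -1.76 without wild type 3. Egr1 rose by 2.04 on the log2 scale, or 2.71 without wild type 2, with overlapping libraries, and its call was lost without rd10 3 (adjusted p = 0.0606, over a range of alternatives from 0.00512 to 0.164). Camera gave an adjusted p of 0.0768 for antioxidants, 0.0505 for the clock and 0.971 for immediate early genes, whose median was 0.02 while the test pointed down. Camera then gave adjusted p = 0.393, adjusted p = 0.393 and adjusted p = 0.988 with an estimated correlation. The antioxidant list passed without wild type 3 (0.0393), rd10 1 (0.0410), the 4 libraries with lens transcripts (0.00684) or wild type 3 and GFP 2 (0.0420) and with the length trend removed (0.00662), over a range of alternatives from 0.00662 to 0.393. The clock list passed with upper quartile scaling (0.0499), without wild type 1 (0.0401), rd10 1 (0.0410) or rd10 2 (0.0347) and with the Xist covariate (0.0477), over a range from 0.0347 to 0.393.

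Markers of tissues near the retina were read as well. Of 11 pigment epithelium genes, 3 rose and 8 did not pass, with 5 higher adjusted over the list alone. Dct, an enzyme of melanin synthesis, rose 2.17-fold. The other genes that rose each lost their call without a single library, such as wild type 3 (adjusted p = 0.0854) or rd10 3 (adjusted p = 0.0558). The list passed camera (adjusted p = 0.00787, and adjusted p = 0.364 with an estimated correlation), but not without wild type 1 (0.0541, over a range of alternatives from 1.15e-07 to 0.364). None of 17 lens genes passed (0), nor adjusted over the list alone, with 1036 ± 1077 CPM of Cryaa in wild type and 756 ± 1309 in rd10 (adjusted p = 0.913). Summed lens CPM was 5907 in wild type 2, 2692 in wild type 3, 6326 in rd10 2 and 5032 in GFP 1, against 57.4 to 157.9 in the other 5 libraries. The lens list did not pass camera (adjusted p = 0.229, and adjusted p = 0.792 with an estimated correlation) but did so downward without rd10 2 (0.00191), without wild type 1 (0.0111) and with library totals (0.0134), over a range of alternatives from 0.00191 to 0.935. Of 15 blood vessel genes, Kdr rose 3.71-fold, Ly6c1 was 2.14-fold lower and 13 did not pass, with 1 and 1 adjusted over the list alone. Ly6c1 lost its call with the length trend removed (adjusted p = 0.0567, over a range of alternatives from 9.06e-04 to 0.292). Of 4 tested muscle genes, Mylpf was 3.93-fold lower and 3 did not pass, with 1 lower adjusted over the list alone. Mylpf lost its call without wild type 3 (adjusted p = 0.0537) and rd10 3 (0.0640), over a range of alternatives from 0.00179 to 0.203. None of 3 oligodendrocyte genes passed (0), nor adjusted over the list alone, with 35.7 ± 2.83 CPM of Mbp in rd10 and 29.4 ± 3.52 in wild type. By camera, the adjusted p was 0.382 for vessel, 0.157 for muscle and 0.624 for oligodendrocyte genes. For these lists in turn it gave adjusted p = 0.718, adjusted p = 0.364 and adjusted p = 0.700 with an estimated correlation. With fry, the muscle list passed downward (0.0430) and the oligodendrocyte (0.0231) and horizontal (0.00300) lists upward, and Mbp passed with library totals (0.0342). Alas2 was the 1 red blood cell gene tested and did not pass over all genes, with a log2 difference of -1.56 and an adjusted p of 0.0764, but it was counted as lower adjusted over the list alone (1). Its log2 difference was -0.78 without wild type 3, which had 4.41 CPM against 1.62 and 1.16 in the other wild type libraries, and ran down to -1.88 without another library.

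Without the 4 libraries with lens transcripts, which leaves wild type 1 as the only wild type library, assumed to vary like the other groups, 86 genes were higher and 457 lower, while 1732 and 1641 were called with the lens transcript level as a covariate. Counts fell more than 1.5 times without wild type 3 (1279 higher), rd10 1 (1269 and 1186), rd10 2 (1369 and 1234) and rd10 3 (1269 and 1271), and with library totals, which shifted the median of all genes to 0.25, 3604 genes were higher and 1077 lower.

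**Figure D2:**
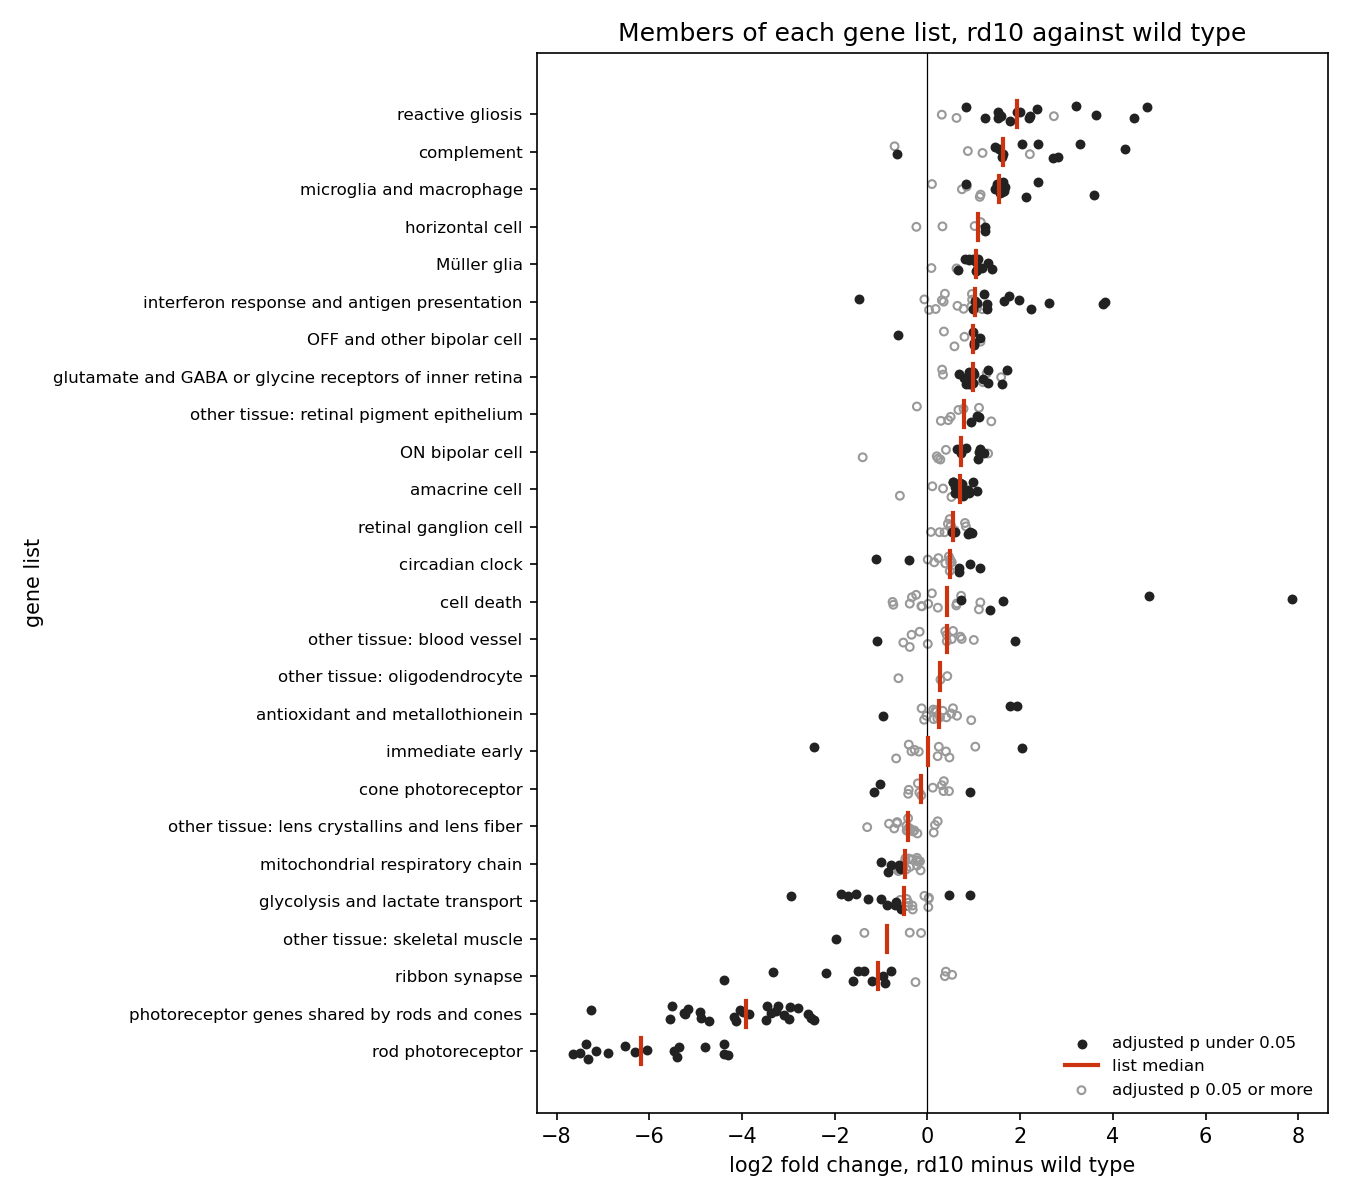
Log2 fold change of rd10 against wild type for each tested gene of each list with at least 3 tested genes, filled where the adjusted p was under 0.05 and open otherwise, with a red bar at the median of the list. The rod list lies around its median of -6.18 and the gliosis list around 1.92, and the point at 7.85 is the fitted value of Casp12, which had no count in wild type.

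The comparison of rd10 with GFP set the same rd10 libraries against a second normal retina. In all, 2174 genes were higher and 2138 lower, of which 972 and 1029 changed at least 2-fold, and the libraries did not overlap for 48.2% of genes, where chance gives 10%. Pde6b fell from 3215 ± 154 CPM in GFP to 19.6 ± 12.3 CPM in rd10 (SD, n = 3), a log2 change of -7.36 with an adjusted p of 4.81e-06. C4b rose 40.9-fold, Serpina3n 24.2-fold, A2m 12.1-fold, C3 10.9-fold, Serping1 8.90-fold and Gfap 8.15-fold.

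Gnat1 and Nrl were 171.5-fold and 198.8-fold lower than in GFP. Hdc, Nipal1, Sh2d1a and Slc17a3 had ratios of counts per total of 319 (exact 95% interval 108.6 to 1548), 298 (82.1 to 2471), 236 (65.0 to 1959) and 311 (55.2 to 12310). Opn1sw was 1.88-fold lower and Grm6 2.32-fold higher. Opn1mw, Arr3 and Gng13 did not pass, with log2 differences of -0.03, 0.16 and 0.22, and Opn1mw turned to 0.30 with library totals. Gng13 passed without GFP 2 (0.64, adjusted p = 0.0467) and with the length trend removed (0.71, adjusted p = 0.00564), over a range of alternatives from 0.00564 to 0.961. Glul rose by 0.61 on the log2 scale, or 1.53-fold, with an adjusted p of 0.0279. The call was lost without rd10 1 (0.0731), rd10 2 (0.0607), rd10 3 (0.0649) or GFP 1 (0.0586), where the log2 change was 0.60, 0.65, 0.62 and 0.56. It was also lost without the 4 libraries with lens transcripts (0.176) and with the Xist (0.0661) or lens (0.0529) covariate, over a range of alternatives from 0.00119 to 0.176.

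All 16 rod genes and all 26 shared photoreceptor genes fell, with medians of -6.26 and -4.00. Of the cone list, 3 rose, 3 fell and 7 did not pass. The numbers that rose were 8 of 13 for ON bipolar cells, 5 of 9 for OFF and other bipolar cells, 2 of 6 for horizontal cells, 12 of 17 for amacrine cells, 7 of 14 for ganglion cells and 15 of 21 for inner retinal receptors. They were 12 of 15 for Müller glia, 14 of 19 for gliosis, 15 of 20 for microglia, 12 of 15 for complement and 19 of 27 for the interferon list, and 1 gene fell in each of the OFF bipolar, complement and interferon lists. In glycolysis 9 of 22 fell and 2 rose, in the respiratory chain 7 of 22 fell, and in the ribbon synapse 9 of 14 fell. Of the cell death list 5 rose and 1 fell, of the clock list 3 rose and 2 fell, and of the pigment epithelium list 4 rose. Adjusted over the list alone, 16, 26, 9, 7 and 10 genes were lower in the rod, shared, glycolysis, respiratory chain and ribbon lists. Higher genes adjusted over the list alone were 8 for ON bipolar, 13 for amacrine, 11 for ganglion, 13 for Müller, 17 for gliosis, 19 for microglia, 12 for complement and 21 for interferon genes.

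Camera gave 13 lists as higher and 5 as lower. They were the 12 and 5 lists of the comparison with wild type and, as a further one, the antioxidant list (adjusted p = 0.0494, and adjusted p = 0.382 with an estimated correlation), where Sod3 and Gpx3 rose and Gpx4 fell. The antioxidant call was lost without rd10 3 (0.0823), GFP 1 (0.139), GFP 3 (0.0880) or the 4 libraries with lens transcripts (0.0974) and with the Xist covariate (0.0579), over a range of alternatives from 0.00732 to 0.382. That of cell death (adjusted p = 0.0186, and adjusted p = 0.181 with an estimated correlation) was lost without GFP 1 (0.0595) or the 4 libraries (0.0974), over a range from 0.00121 to 0.181. Horizontal and oligodendrocyte lists passed with fry alone (0.00718 and 0.00457). With an estimated correlation the smallest value of any list was adjusted p = 0.0730, so none passed (0). By fry, each list that camera called passed except the respiratory chain. The respiratory chain call ended with fry (0.0600) and with the length trend removed (0.181), over a range of alternatives from 1.86e-05 to 0.478. For the lens list the median was 0.36 and the mean 0.16, while the test, which did not pass, pointed down (adjusted p = 0.641, and adjusted p = 0.916 with an estimated correlation). It passed downward without rd10 2 (0.0215, median -6.83) and with the lens covariate (0.0205, median -0.85), and pointed up without rd10 1, rd10 3 or GFP 1, where the median was 0.89, 0.90 and 3.94.

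Without the 4 libraries with lens transcripts, 876 genes were higher and 970 lower, and 1925 and 1882 with the lens level as a covariate. Counts fell more than 1.5 times without rd10 1 (1297 and 1305), rd10 2 (1416 and 1367), rd10 3 (1299 and 1408) and GFP 3 (1353 higher), and the split turned to 4041 higher and 1055 lower with library totals, which shifted the median of all genes to 0.31, and to 2745 and 1644 with upper quartile scaling.

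Of the called genes, 1708 were higher and 1752 lower in rd10 against both normal groups, and none was called in opposite directions (0). Pde6b, Gnat1 and Nrl were among the lower genes, and Serpina3n, C4b, A2m and Gfap among the higher ones. Independent lists of these sizes would share 314.2 and 297.2 genes. Because the same rd10 libraries enter both comparisons, the covariance of the log2 fold changes was set against 20 simulations with unchanged rd10 libraries. Across genes, which are not independent replicates, it was 0.874 against a mean of 0.0647 in the simulations. The 3 rd10 libraries were not split between the comparisons, so the shared part was not removed.

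The comparison of GFP with wild type set the groups with normal retina side by side, which also differed in age and in the label of genetic background. The mean level of Pde6b was 3215 ± 154 CPM in GFP and 3153 ± 506 CPM in wild type (SD, n = 3), and that of Grm6 114.7 ± 22.6 and 114 ± 22.9 CPM. No gene passed the quasi-likelihood test of edgeR (0 higher and 0 lower), with 214 genes at an unadjusted p under 0.05, and limma-voom also called 0 genes. Libraries did not overlap for 3.99% of genes, where chance gives 10%. DESeq2 called 1 gene, Ifit3, an interferon-induced gene, as lower in GFP (log2 change -2.20, adjusted p = 0.0377), with counts of 81, 99 and 286 in wild type and 30, 43 and 25 in GFP.

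Without GFP 3, 4 genes were called higher, named here after their values were seen: Lmf1 (log2 change 2.87), Narfl (1.77), Haghl (1.65) and Metrn (1.89), with adjusted p values of 0.0212, 0.0212, 0.0315 and 0.0315. They lie within 217.9 kb around Gng13 on chromosome 17. Gng13 itself had 178 ± 77.9 CPM in GFP and 157.8 ± 44.9 CPM in wild type (SD, n = 3), a log2 difference of 0.17 with an adjusted p of 1 that turned to -0.22 without GFP 2.

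Of the 26 lists tested, the interferon list alone passed camera, as lower in GFP with a median log2 fold change of -0.36 (adjusted p = 3.74e-06, and adjusted p = 0.737 with an estimated correlation). None of its 27 genes passed over all genes (0), and 1 was lower adjusted over the list alone. Its call was lost without wild type 3 (0.430) and with fry (0.948), and it pointed up without the 4 libraries with lens transcripts (0.781), over a range of alternatives from 2.11e-08 to 0.948. The microglia list passed downward with relative log expression scaling (0.0494), with the length trend removed (0.0411), without wild type 1 (0.00186) or GFP 2 (0.0159) and without wild type 3 and GFP 2 (0.00738), over a range from 0.00186 to 0.948. Ifit3 of the interferon list had 28.7 CPM in wild type 3 against 8.18 and 9.53 in the other wild type libraries. B2m, the most abundant gene of the interferon list, had 44.2 ± 12.02 CPM in GFP and 51.3 ± 18.5 in wild type (adjusted p = 1), and it overlaps Patl2. The median of the rod list was 0.07 and that of the cone list -0.17, neither past camera (adjusted p = 0.589 and adjusted p = 0.104, and adjusted p = 0.911 and adjusted p = 0.737 with an estimated correlation). The cone list passed downward without GFP 2 (0.0226) and without wild type 3 and GFP 2 (0.0353), over a range of alternatives from 0.0226 to 0.948. In simulated data of this design the gene test recovered 34.3% of genes changed 2-fold.

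**Figure D3:**
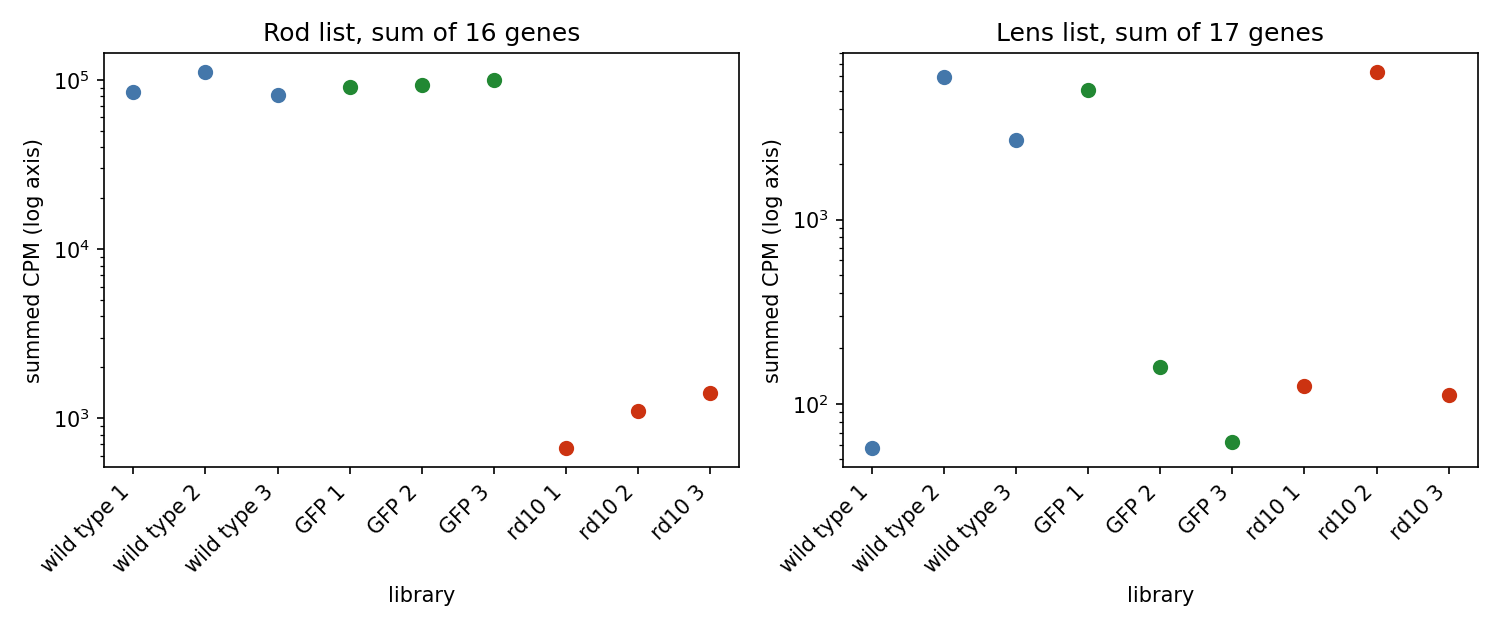
Summed CPM (log axis) per library of the 16 rod genes and of the 17 lens genes, with 1 point per library and colours for wild type, GFP and rd10. The rod sums of the rd10 libraries were 663, 1100 and 1409 CPM, and the lens sums were 2692 to 6326 CPM in 4 libraries drawn from all 3 groups.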

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

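Of the alternatives here, 5 were chosen after the data were seen: leaving out the 4 libraries with lens transcripts, the lens level as a covariate, leaving out wild type 3 and GFP 2, removing the length trend, and the Xist covariate. The others were fixed before the data were examined. For 120 pairs of a named gene and a comparison, 2520 alternative values were computed: 2398 kept direction and side of the threshold, 94 lost the call, 4 gained one and 24 changed direction, none of these 24 for a gene past the threshold at first (0). Of 109 pairs past the threshold, 11 lost the call without at least 1 single library, 6 in another alternative and 53 without the 4 lens libraries. The cause of a change was not tested unless given. The floor of 3 counts per library was a set value, and depth decides which CPM it stands for. With 3 libraries per group, changes of 2-fold were mostly missed in simulations where few genes changed.

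Library totals, which by construction carry the loss of rod counts into all other genes, gave 3604 higher and 1077 lower genes in rd10 against wild type (2114 higher at least 2-fold), 4041 and 1055 against GFP (2407 and 645 at least 2-fold), and 3297 and 933 against both. Arr3 turned to 0.055 and Opn1mw to 0.11 against wild type, and Opn1mw to 0.30 against GFP. Against GFP, Opn1mw also turned to 0.068 with upper quartile scaling, 0.01 with limma-voom (0.0067) and 0.01 with the replicate block (0.0097). Relative log expression scaling gave 2 lists lower in GFP against wild type, and DESeq2 called 1 gene lower there, at least 2-fold. DESeq2 called 2531 higher and 2233 lower genes in rd10 against wild type and 2570 and 2470 against GFP, and limma-voom 2273 and 2014, and 2420 and 2084.

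The numbers of the replicates did not pair the samples, since deviations of libraries with the same number correlated between -0.37 and 0.36. With the replicate block, 1817 genes were higher and 1789 lower in rd10 against wild type, 1996 and 1912 against GFP, and 0 and 0 in GFP against wild type. Camera with an estimated correlation called 0 lists in any comparison, and fry 0 lists lower in GFP against wild type.

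Without the 4 lens libraries, which leaves 1 wild type library assumed to vary like the other groups, rd10 against wild type gave 86 higher and 457 lower genes, all of these at least 2-fold (86 and 457), rd10 against GFP 876 and 970, and both 75 and 454. In GFP against wild type it gave 3 lists higher and 0 lower. Opn1mw turned to 0.24 against wild type and B2m to 0.42 in GFP against wild type. Fewer samples lower the power, and with the lens level as a covariate in all 9 libraries 1732 and 1641 genes were called against wild type, 1925 and 1882 against GFP, and 0 and 0 in GFP against wild type. Without wild type 3 and GFP 2, 2373 and 2320 genes were called against wild type and 2434 and 2312 against GFP. Arr3 turned to 0.26, Opn1mw against GFP to 0.25 and Gng13 in GFP against wild type to -0.23, with 1 list higher and 4 lower there. With the length trend removed, 2533 and 2528 genes were called against wild type and 2704 and 2663 against GFP. Arr3 turned to 0.0016 and Opn1mw to 0.12 against wild type, Opn1mw to 0.28 against GFP, and 2 lists were lower in GFP against wild type. With the Xist covariate 1760 and 1730 genes were called against wild type and 1655 and 1667 against GFP.

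Leaving out single libraries gave 1269 to 1809 higher and 1186 to 1711 lower genes in rd10 against wild type, 1297 to 2175 and 1305 to 2097 against GFP, and 973 to 1807 and 1081 to 1767 against both. In GFP against wild type it gave 0 to 4 higher genes, 0 to 3 lists higher and 0 to 6 lists lower. Arr3 against wild type ran from -0.49 to 0.26, Cryaa from -11.83 to 0.67, Opn1mw against GFP from -0.18 to 0.25, B2m in GFP against wild type from -0.38 to 0.12 and Gng13 there from -0.22 to 0.40.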

Other observations

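The tests on lens transcripts, on the genes around Gng13 and on the 2 parts of the glia and immune lists were chosen after the results were seen, as was the second form of the first Gng13 test. Rod transcripts did not fall to one common share in the rd10 libraries. As a percentage of the wild type mean, the median of the 16 rod genes was 0.748, 1.42 and 2.13 in rd10 1, 2 and 3, and the ratio of the 90th to the 10th percentile was 21.5, 7.09 and 6.13. Gnat1, Nrl and Pde6b stood at 0.158% to 0.191% in rd10 1, while Gngt1 stood at 5.09% and Cngb1 at 4.25%. For 12 of the 16 genes the libraries had the same order. The last of these ratios and this count had been computed as tests of 2 technical explanations, which are not weighed here.

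Xist was found at 738 CPM in wild type 2 and 1407 CPM in rd10 1 and at most at 2.06 CPM in the other 7 libraries, and Ddx3y, Eif2s3y, Kdm5d and Uty of the Y chromosome had counts of 0 in those 2 libraries alone. Loadings of genes on the second principal component correlated with transcript length across genes, which are not independent replicates (Spearman 0.542), and after removal of each library's length trend this component held 16.4% of the variance.

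Most lists of inner retinal neurons, glia and immune cells were higher in rd10 than in wild type by camera with its preset correlation. The horizontal list was not past the threshold (0.0689), and none of the lists was with an estimated correlation (0.0607 to 0.186). The rod list, of which all 16 genes fell, did not pass that test either (0.0607). By fry, which does not compare a list with other genes, all lists of inner retinal neurons, glia and immune cells passed upward. Its values ran from adjusted p = 8.38e-05 for amacrine cells to adjusted p = 0.00397 for the interferon list. The pooled median of 65 genes of the ON bipolar, amacrine, ganglion, horizontal and Müller lists was at least 0.76 (bootstrap SE 0.0720, over genes) over 5 scalings. These scalings moved the median of all genes only from -0.03 to 0.25, so they could not have removed that difference. None was anchored to the RNA per retina, and a dependence on such a scaling was not tested. A lower share of rod RNA, which would raise all other cell types alike, may account for the higher inner retinal lists, since the 5 list medians ranged over 0.53 with p = 0.060 in 10000 permutations of genes, although a p above the threshold does not show equal medians, and the cone list was not raised (median -0.13). The same explanation is argued against for the 50 genes of the gliosis, microglia and complement lists, whose median of 1.60 exceeded that of the inner retinal genes by 0.83, with p = 1.0e-04, the smallest that the permutations can give. The permutations took genes as independent, while their estimated correlation was 0.254 for gliosis, 0.0783 for microglia and 0.245 for complement. Their p values describe spread over genes, not over mice, and are likely too small. The explanation stays open for the 27 interferon genes, whose median of 1.03 exceeded that of the inner retinal genes with permutation p = 0.0460 but lay within the 5 list medians (0.56 to 1.08). That bound on the list medians was added after this p was seen. All 77 genes together, the test fixed first, also gave permutation p = 1.0e-04 with a median of 1.51. A change of these cells with genotype or with age, which coincide here, stays open and was not tested.

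Lens transcripts were abundant in wild type 2, wild type 3, rd10 2 and GFP 1, where Cryaa had at least 955 CPM against at most 10.4 CPM in the other 5 libraries. A response of the retina to rod loss is argued against, since 4 of the 6 normal libraries had more summed lens CPM than the lowest rd10 library. Lens tissue carried over at dissection may be the source and stays open. For 11 of 12 other lens genes the ratio to Cryaa had an SD under 1 on the log2 scale over the 4 libraries, with a median SD of 0.22 (range 0.14 to 1.07, the highest for Lenep). The lowest Cryaa level of the 4 was 91.6-fold above the highest of the other 5, short of the 100-fold that the test asked for. Of the 17 lens genes, 2 were at 1 CPM or more in each of the other 5 libraries and none (0) stood in another list. Removing the 4 libraries lowered the counts of rd10 against wild type to 86 and 457, while with the lens level as a covariate they were 1732 and 1641.

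From Lmf1 to Metrn on chromosome 17 (25716119 to 25933990, 217.9 kb), the 7 genes of at least 5 CPM besides Gng13 had log2 ratios to the wild type mean of 0.96 to 2.64 in GFP 1, 0.34 to 3.14 in GFP 2 and -0.80 to 0.13 in the library labelled GFP 3, while the neighbour Sox8 stood at 0.17, 0.36 and -0.04. Gng13, the most abundant gene there, stood at -0.37 in GFP 1, 0.80 in GFP 2 and -0.04 in GFP 3. No wild type library showed the raised segment, the highest median of a wild type library in the window being 0.32. The segment was found through genes called higher in GFP 1 and GFP 2 than in wild type, which favours low wild type values. The test therefore does not decide on an exchange of GFP 3 with a wild type library, which stays open. Extra copies of this segment in GFP 1 and GFP 2 stay open: of 14162 windows of 7 neighbouring genes, the highest shared genes with it in both, 0.60 above the highest elsewhere in GFP 1 (1.43 against 0.83) and by more in GFP 2 (1.69 against 0.87). Since the segment was found through genes raised in these libraries, this margin describes it and does not favour extra copies over another local cause. That margin replaced, after its result was seen, a test on the rank of the best window holding Gng13, which was 1 in GFP 1 and 6 in GFP 2, behind windows that overlap the same segment, and which had left the question open. Gng13 was not raised in GFP 1, but an RNA level does not count gene copies, so this decides nothing about extra copies in that library. With a median of -0.038, GFP 3 may come from mice without such copies, or from a wild type or outside sample with a wrong label. These data do not separate the possibilities, and the transgene itself was not analysed here. Over the tested genes, log2 CPM of GFP 3 correlated at 0.9781, 0.9704 and 0.9575 with wild type 1, 2 and 3. With GFP 1 and GFP 2 it correlated at 0.9714 and 0.9456.

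With 3 libraries against 3 there are 10 splits of the libraries, too few for a share under 0.05. For rd10 against wild type 1 of the 10 splits gave as many genes (4055, the highest of the others 0), and for rd10 against GFP 1 of 10 (4312, the highest of the others 0). For GFP against wild type all 10 of 10 splits gave at least as many as the real count of 0, and the highest was 555 for wild type 1, GFP 1 and GFP 3 against wild type 2, wild type 3 and GFP 2, which points to a structure of the samples. The deviations of these libraries from their group mean correlated with transcript length across genes at 0.557, 0.486 and 0.294 in the first 3 and at -0.132, -0.467 and -0.523 in the others (Spearman).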
